A study of Mus musculus with 9 samples.

How the data were processed

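Gene expression was measured on 9 Affymetrix mouse arrays, 1 per RNA sample. Per the labels, bone marrow cells of the C57BL/6 background had been immortalised with HoxA9, a homeobox transcription factor used as a leukemia oncogene in mouse models. The cells were infected with a retrovirus and injected into irradiated mice, and 4 weeks later cells positive for green fluorescent protein were sorted from the bone marrow. There were 3 groups of 3 arrays. CTL cells carried the empty EGFP vector, IDH1wt cells a vector with wild-type IDH1, and IDH1mut cells one with mutant IDH1. IDH1 is the cytosolic isocitrate dehydrogenase, and its cancer mutants make 2-hydroxyglutarate from 2-oxoglutarate. Per the labels' protocols, 3 µg of total RNA was made into biotin-labelled target.

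The deposited values were log2 expression values per probe set, ranging from 1.72 to 14.2. RMA, which corrects background, quantile-normalises arrays and summarises probe sets, is the only step named in the submitters' processing notes, with no version. Scale was read from the values: the array medians lay between 4.65 and 4.72, and the upper quartiles between 6.91 and 7.00. The table held 20877 probe sets and 0 control probe sets. With an annotation of 2016, 17815 probe sets had 1 gene symbol, 244 had several and 2818 had none, and the last 2 kinds were left out of the gene tests. Gene identifiers of 17668 single-symbol probe sets matched the reference gene table, and 0 symbols needed an update. Nearly every gene, 17649 of 17731, had 1 probe set. The step that reduced the array to about 1 probe set per gene is not given in the sources used here. RMA gives no detection call, and folds of genes near the low end of the scale are compressed.

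For each gene the probe set with the highest mean over the 9 arrays was kept. A linear model with a mean per group was fitted to all 9 arrays with limma 3.58.1 in R 4.3.3, and the moderated contrasts IDH1mut against CTL, IDH1wt against CTL and IDH1mut against IDH1wt were tested two-sided. Benjamini-Hochberg adjustment ran over the 17731 genes of each contrast, with a threshold of 0.05. All adjusted p-values of genes below come from this limma fit, and a fold change is a difference of mean log2 values ± its moderated standard error (SE). "Rose", "fell" and "changed" mark genes past the threshold. Group means of log2 values are given ± SD.

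Lists of genes, 31 in number, were fixed before the data were examined. The lists on CDK inhibitors, on the cell cycle (G1/S and DNA replication, G2/M and mitosis) and on ERK MAPK output were chosen knowing that the published study of these mice wrote about the cell cycle and MAPK. The others covered marrow cell types, cell types a sort of fluorescent marrow cells could hold, and pathways tied to isocitrate dehydrogenase. Each list was tested with camera (limma) at a preset inter-gene correlation of 0.01, two-sided, with adjustment over the 31 lists. An estimated correlation and fry, which asks whether the members move one way on balance without setting them against other genes, were run beside it. Calls of members were counted over all genes and adjusted over the list alone.

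The genes named were set by rule before the data were examined. In each comparison these were the 12 genes with the largest rise and the 12 with the largest fall among changed genes whose arrays did not overlap between the groups, leaving out clone-like symbols. Up to 4 members of each described list were added, led by changed members of largest size. Of those, members whose call did not hang on a single array were preferred in the text after the values were seen. Idh1, Idh2, Hoxa9, Meis1, Cdkn2a, Cdkn2b and Cdkn1a were always included; Cdkn2c had been listed too and had no probe set in the table used here. A few members that moved against their list, Hspa8 and Dnajb4 are named as well and were chosen after their values were seen, as were the 12 genes drawn.

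The procedure was tested on simulated IDH1mut and CTL data of 17731 genes, 200 altered, with means and residual spreads over all 9 arrays. It recovered 30% of altered genes at a log2 size of 0.5, 90% at 1, 94% at 2 and 100% at 3. False calls made up 6 of 163. In these simulations 2 lists shifted by 0.5 were called by camera with either correlation and by fry. Genes were drawn independently of each other. List calls were therefore not tested for members that move together, such as the erythroid genes (estimated correlation 0.668 in the real data).

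Because both IDH1 groups were compared with the same 3 CTL arrays, 20 sets of 9 unchanged arrays were simulated. In each set the simulated CTL arrays were likewise shared by both comparisons. The alternatives tried were the mean of a gene's probe sets, all probe sets one by one, the brighter genes by mean, a repeated quantile normalisation, centring of each array, a fit on the 6 arrays compared, another spread model, array weights, the replicate number as a block, an added fold threshold, an unmoderated test per gene, and leaving out each array in turn. Intervals of medians came from 10000 bootstrap draws over genes, or 2000 for chromosomes. Figures were drawn with matplotlib 3.10.9, and tables were prepared with pandas 2.3.3 and numpy 2.4.6 in Python 3.11.15.

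Precision was limited by the number of arrays, 3 per group, with a median SE of 0.119 per log2 fold change. The labels name replicates without saying that they came from separate mice, so p-values measure the spread between these samples, which may be technical. Per the labels no batch or scan date is known, and a batch shared by all arrays of a group could not be told apart from the group.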

Results

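The data described sorted, vector-carrying bone marrow cells 4 weeks after transplantation, with 3 arrays each for empty vector (CTL), wild-type IDH1 (IDH1wt) and mutant IDH1 (IDH1mut). The comparisons asked what mutant IDH1 changed in HoxA9-immortalised cells in vivo, and whether wild-type IDH1 did the same. Correlations between arrays of a group ran from 0.992 to 0.997 over genes, and those between CTL and IDH1mut arrays from 0.983 to 0.986. The first principal component held 44.7% of the variance and set the IDH1mut arrays apart from the rest. The second component, with 17.7%, set the IDH1wt arrays apart.

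**Figure D1:**
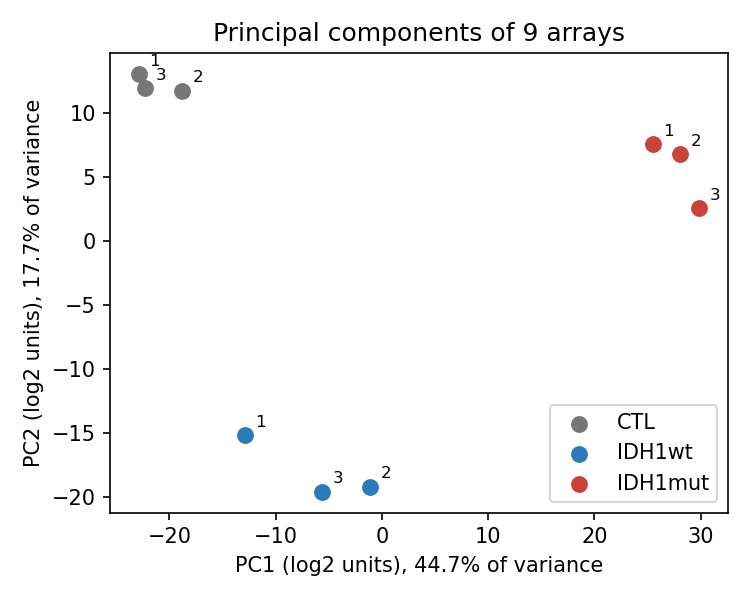
Principal components of the 9 arrays over all genes, in log2 units, with each point 1 array labelled by its replicate number. The 3 groups lie apart, along the first component (44.7% of variance) for IDH1mut and the second (17.7%) for IDH1wt.

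Mouse Idh1 read 10.67 ± 0.03 (SD, n = 3) in CTL, 10.58 ± 0.13 in IDH1wt and 10.64 ± 0.17 in IDH1mut, and did not pass in any comparison. Its log2 fold change was -0.03 ± 0.11 (SE) in IDH1mut against CTL (adjusted p = 0.888) and -0.09 ± 0.11 in IDH1wt against CTL (adjusted p = 0.733). The labels do not say which species the IDH1 insert came from or whether it holds the probed part, so this probe set checks no label. Hoxa9, the gene used for immortalisation, read 3.74 ± 0.20 in CTL, 3.89 ± 0.28 in IDH1wt and 3.35 ± 0.04 in IDH1mut, below the array medians. The same limit of construct and probe applies to it.

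In IDH1mut against CTL, 16 of 21 genes of late neutrophil maturation rose and 11 of 14 genes of the primary granule list fell. Primary granules are made earlier in the same lineage, and their list also holds the transcription factor genes Cebpa and Gfi1. Both lists were called at the preset correlation, and neither passed with an estimated one (adjusted p = 0.162 for each). Mmp8, neutrophil collagenase, was 4.50-fold higher (log2 fold change 2.17 ± 0.14, SE, n = 3 against 3; adjusted p = 5.87e-06), and Elane, neutrophil elastase, was 2.20-fold lower (-1.14 ± 0.11; adjusted p = 7.63e-05). Of 22 erythroid genes 18 rose, and of 30 interferon response genes 15 rose and 2 fell, as lists that likewise did not pass with an estimated correlation (adjusted p = 0.379 and 0.378). Sall2, a zinc finger transcription factor, rose most, 26.5-fold (4.73 ± 0.20), from 2.62 ± 0.13 to 7.35 ± 0.49. Cdkn2a, which encodes the cell cycle inhibitors p16Ink4a and p19Arf, fell 5.32-fold (-2.41 ± 0.21; adjusted p = 3.73e-05).

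Of 17731 genes, 3663 changed between IDH1mut and CTL, 1784 up and 1879 down. Among the 413 that changed at least 2-fold, 299 rose and 114 fell. Arrays of the 2 groups did not overlap for 37.8% of all genes, where chance gives 10%. Without CTL replicate 1 the count was 2370, and an unmoderated test per gene gave 2074.

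The largest rises after Sall2 were those of Bex1 (10.4-fold), Lrmda (10.3-fold), Mecom (7.60-fold), Slc15a2 (7.46-fold), Scrg1 (6.57-fold), Ovgp1 (6.29-fold) and Chil1 (5.98-fold). Prrt4 (5.65-fold), Socs2 (5.59-fold), Aldh1a1 (5.31-fold) and Id2 (5.21-fold) followed, and the adjusted p of the 12 ran from 2.73e-07 to 0.00127. Mecom encodes EVI1, a transcription factor of hematopoietic stem cells, and went from 4.67 ± 0.30 to 7.59 ± 0.12. The Mecom locus is a known site of retroviral integration, and neither integration sites nor a shared founder clone of the IDH1mut replicates were analysed here. The rises of Mecom and Sall2 therefore cannot be assigned to the mutant enzyme. The same limit holds for the other differences of the IDH1mut and IDH1wt groups. Socs2 encodes a suppressor of cytokine signalling, and Id2 an inhibitor of basic helix-loop-helix factors. The largest falls were those of Hspa1a (19.5-fold), Hspa1b (12.2-fold), Rhoj (8.63-fold), Dsp (8.28-fold), Jun (6.15-fold) and Mansc1 (5.32-fold). Egr1 (4.73-fold), Eya1 (4.67-fold), As3mt (4.58-fold), Acyp2 (4.30-fold) and Dleu7 (4.22-fold) completed the 12 with Cdkn2a, at adjusted p from 7.57e-07 to 0.0016. Hspa1a and Hspa1b encode the inducible HSP70 and are near-identical copies, so their separate values are uncertain.

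**Figure D2:**
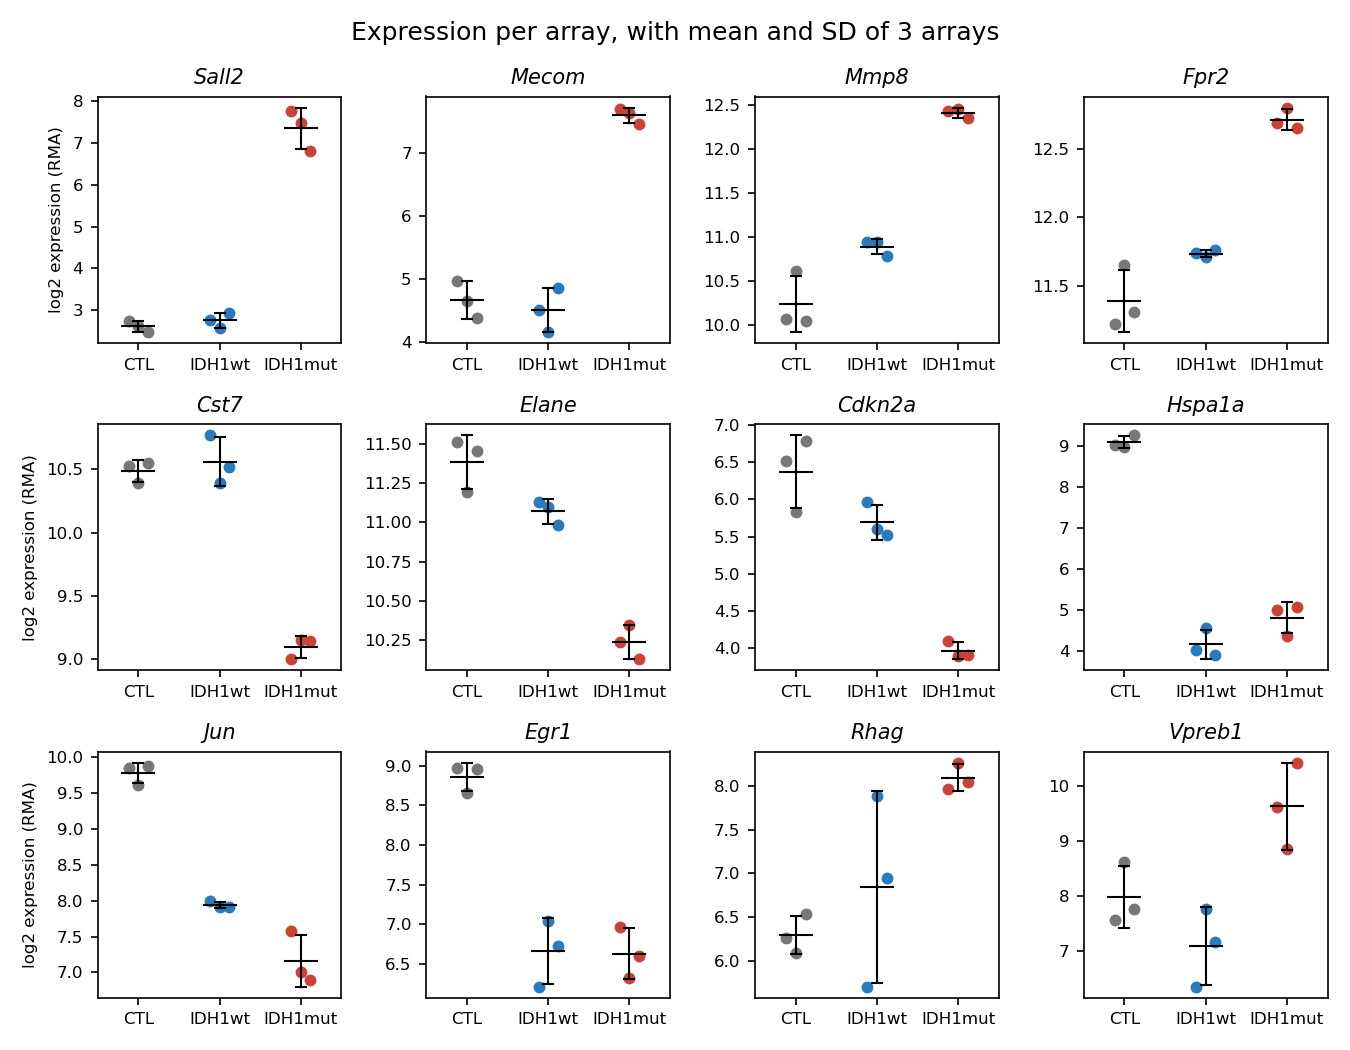
Log2 expression (RMA) of 12 genes on each of the 9 arrays by group, with bars for the mean and SD of 3 arrays and a separate axis range per gene. Sall2 and Mecom are high only on IDH1mut arrays among these 9, Hspa1a, Jun and Egr1 are high only on CTL arrays, and Rhag varies widely among IDH1wt arrays.

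Late neutrophil genes rose in 16 of 21 measured members, with 0 fallen (16 and 0 adjusted over the list alone) and a median log2 fold change of 0.57. Besides Mmp8, Fpr2, a formyl peptide receptor, rose by 1.32 ± 0.11, Anxa1 by 1.25 ± 0.20 and the chemokine receptor Cxcr2 by 1.03 ± 0.13 on the log2 scale. The list was called by camera (adjusted p = 3.26e-12; adjusted p = 0.162 with an estimated correlation). Primary granule genes fell in 11 of 14 members and 0 rose, with the same counts adjusted over the list alone and a median of -0.66. Cst7 (-1.39 ± 0.11) and Nkg7 (-1.03 ± 0.10) fell along with Elane. This list was called as well (adjusted p = 6.7e-08; adjusted p = 0.162 with an estimated correlation).

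Erythroid genes rose in 18 of 22 members and fell in 0 (20 and 0 adjusted over the list alone), with a median of 1.18. Rhag, a red cell membrane protein, rose by 1.81 ± 0.40 and Hemgn by 1.72 ± 0.33 on the log2 scale. Camera called the list (adjusted p = 4.33e-10; adjusted p = 0.379 with an estimated correlation). The members' median deviation from their means over all arrays was 0.51, 0.81 and 0.53 on the IDH1mut arrays and between -0.52 and -0.48 on the CTL arrays. On the IDH1wt arrays it spread from -0.72 to 0.53.

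Interferon response genes rose in 15 of 30 members and fell in 2 (18 and 4 adjusted over the list alone), with a median of 0.40. Ifit3 rose by 1.61 ± 0.13, Rsad2 by 1.37 ± 0.11, Ifit1 by 1.17 ± 0.11 and Oasl2 by 1.13 ± 0.13, all of them antiviral genes. Bst2 (-0.99 ± 0.16) and Gbp3 (-0.77) fell. The call (adjusted p = 6.34e-07) was lost with an estimated correlation (adjusted p = 0.378 with an estimated correlation).

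Targets of MYC and genes of ribosome biogenesis fell in 10 of 29 members and rose in 1 (14 and 1 adjusted over the list alone), at a median of -0.25. Mybbp1a (-0.76 ± 0.12), Utp20 (-0.56 ± 0.13) and Myc itself (-0.47 ± 0.10) fell, whereas Tfrc, the transferrin receptor, which the erythroid list also holds, rose by 1.17 ± 0.21. The list was called at adjusted p = 0.00186 (adjusted p = 0.378 with an estimated correlation). Immediate early and stress genes fell in 6 of 16 members and rose in 1 (7 and 1 adjusted over the list alone), with a median of -0.18 and a mean of -0.90 set by Hspa1a (-4.29 ± 0.20), Hspa1b (-3.61 ± 0.28), Jun (-2.62 ± 0.16) and Egr1 (-2.24 ± 0.21). Klf6 rose by 0.53. Its call (adjusted p = 0.0474; adjusted p = 0.77 with an estimated correlation) was lost without CTL replicate 3 (adjusted p = 0.06), IDH1mut replicate 2 (adjusted p = 0.133) or IDH1mut replicate 3 (adjusted p = 0.092), among the brighter genes alone (adjusted p = 0.252) and in a fit on the 6 arrays compared (adjusted p = 0.0788). The median was -0.27, -0.11 and -0.12 without IDH1mut replicates 1, 2 and 3 in turn. The list's median deviation was 0.19 on IDH1mut replicate 1, near the CTL arrays (0.24 to 0.27), and -0.14 and -0.23 on IDH1mut replicates 2 and 3.

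The other 25 lists were not called by camera in IDH1mut against CTL. Fry, which does not set members against other genes, called 14 of the 31 lists, 6 of them also called by camera. It added CDK inhibitors and Hox-A genes and partners (each adjusted p = 0.00222) as lower. Unfolded protein (0.0192), dendritic cell (0.0228) and sex-linked genes (0.0274) were lower with fry too. By the same test p53 targets (0.00358), NRF2 genes (0.0126) and T and NK cell genes (0.0422) were higher. Among CDK inhibitors, 2 of 5 members fell and 0 rose (2 and 0 adjusted over the list alone). These were Cdkn2a and Cdkn1a (-0.36 ± 0.11; adjusted p = 0.036), while Cdkn2b (0.05 ± 0.11; adjusted p = 0.795) did not pass. The call of Cdkn1a was lost on leaving out any 1 of 5 single arrays, at adjusted p up to 0.128 (without IDH1mut replicate 2). Of 27 genes for G1/S and DNA replication, 3 rose and 4 fell (3 and 4 adjusted over the list alone), with a median of -0.02 and a mean of 0.01. Ccne1 (0.60 ± 0.17) and Slbp (0.53 ± 0.14) rose, and Mcm3 (-0.50 ± 0.10) and E2f1 (-0.45 ± 0.10) fell. The call of Ccne1 was lost without any 1 of 5 single arrays (adjusted p up to 0.0815, without IDH1mut replicate 1), and that of Slbp without CTL replicate 2 or IDH1mut replicate 2 or 3 (up to 0.0714). Of 27 genes for G2/M and mitosis, 4 rose and 0 fell, the same adjusted over the list alone, with a median of 0. The calls of these 4 (Cenpa, Prc1, Hmmr and Ccna2) were each lost without CTL replicate 2, at adjusted p from 0.065 to 0.0994. ERK MAPK output genes rose in 2 of 18 and fell in 4 (3 and 4 adjusted over the list alone): Dusp6, a phosphatase acting on ERK, rose by 0.85 ± 0.10, and Spry2, an inhibitor of receptor kinase signalling, fell (-1.07 ± 0.16).

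Stem and progenitor genes rose in 7 of 20 and fell in 5, the same adjusted over the list alone. The list's median deviation was -0.13 on IDH1mut replicate 1, below the CTL arrays (-0.05 to -0.03). On IDH1mut replicates 2 and 3 it was 0.33 and 0.21. Meis1, a cofactor of HOXA9, rose by 1.10 ± 0.16 (adjusted p = 0.000749) and Slamf1 by 0.98 ± 0.18, besides Mecom. The group means of Meis1 were 3.47 ± 0.15 in CTL and 4.57 ± 0.33 in IDH1mut, both below the array medians, and its presence was not tested. Hox-A genes and partners rose in 2 of 12 and fell in 4 (2 and 5 adjusted over the list alone), with Pbx3 at -0.92 ± 0.16. Hoxa9 did not pass (-0.39 ± 0.14; adjusted p = 0.0809). For the TCA cycle and 2-hydroxyglutarate enzymes, 2 of 28 rose and 3 fell, the same adjusted over the list alone: Idh2, the mitochondrial isocitrate dehydrogenase, fell (-0.66 ± 0.10; adjusted p = 0.000727), as did Fh1 (-0.58 ± 0.10), and Me2 (0.33) and Got1 (0.44) rose, Got1 with a call lost without CTL replicate 1 (adjusted p = 0.0506). The 2-oxoglutarate dioxygenases, whose cosubstrate is the substrate of mutant IDH1, rose in 3 of 34 and fell in 5, the same adjusted over the list alone. Their median was 0.03 and their mean -0.01, with Kdm6a at 0.95 ± 0.21 and Egln1 at -0.60 ± 0.10.

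Monocyte genes rose in 2 of 18 and fell in 5 (2 and 8 adjusted over the list alone), led by Cd14 (-1.48 ± 0.18), and macrophage genes rose in 4 of 21 and fell in 4 (7 and 4 adjusted over the list alone). Dendritic cell and MHC class II genes rose in 2 of 17 and fell in 5 (2 and 7 adjusted over the list alone). Megakaryocyte and platelet genes rose in 3 of 15 and fell in 1, the same adjusted over the list alone. Mast cell, basophil and eosinophil genes rose in 2 of 19 and fell in 5, the same adjusted over the list alone, with Prg2, an eosinophil granule protein, at -2.06 ± 0.29. T and NK cell genes rose in 5 of 21 and fell in 1 (6 and 1 adjusted over the list alone). Stromal and endothelial genes rose in 3 of 20 and fell in 2 (4 and 4 adjusted over the list alone).

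B cell genes rose in 4 of 22 and fell in 0, the same adjusted over the list alone: Dntt (1.69 ± 0.40), Vpreb1 (1.64 ± 0.42) and Igll1 (1.46 ± 0.37), which act in B cell precursors, and Bank1 (0.55 ± 0.14). The calls of Vpreb1 and Igll1 were each lost on leaving out CTL replicate 1, CTL replicate 3 or IDH1mut replicate 3, at adjusted p up to 0.0739 for Vpreb1 and 0.068 for Igll1. Bank1 lost its call without CTL replicate 1, CTL replicate 3 or IDH1mut replicate 1, at up to 0.0656. The median deviation of the B cell list was highest on IDH1mut replicate 3 (0.72) and CTL replicate 2 (0.61) and lowest on IDH1wt replicate 1 (-0.73).

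Among stress and metabolic pathways, p53 targets rose in 6 of 24 and fell in 3 (8 and 3 adjusted over the list alone), with Ddb2 (0.98 ± 0.13), Fas (0.93 ± 0.10) and Mdm2 (0.56 ± 0.08) up and Rps27l (-0.38) down. NRF2 and NADPH genes rose in 7 of 21 and fell in 1 (8 and 1 adjusted over the list alone). Unfolded protein and ATF4 response genes rose in 4 of 26 and fell in 9 (6 and 12 adjusted over the list alone), with the endoplasmic reticulum genes Sdf2l1 (-0.99 ± 0.12) and Pdia4 (-0.81 ± 0.12) down and Chac1 (0.84 ± 0.12) up. NF-kB and inflammatory genes rose in 7 of 25 and fell in 3 (7 and 5 adjusted over the list alone). Hypoxia and HIF genes rose in 3 of 32 and fell in 6 (3 and 7 adjusted over the list alone), and cholesterol and SREBP genes rose in 2 of 22 and fell in 3, the same adjusted over the list alone. DNA damage response genes rose in 1 of 25 and fell in 3 (1 and 0 adjusted over the list alone), and BCL2 family regulators rose in 1 of 15 and fell in 1, the same adjusted over the list alone. Of 4 sex-linked genes, Xist alone changed over all genes and over the list alone, from 10.24 ± 0.12 to 9.60 ± 0.07 (-0.65 ± 0.11).

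**Figure D3:**
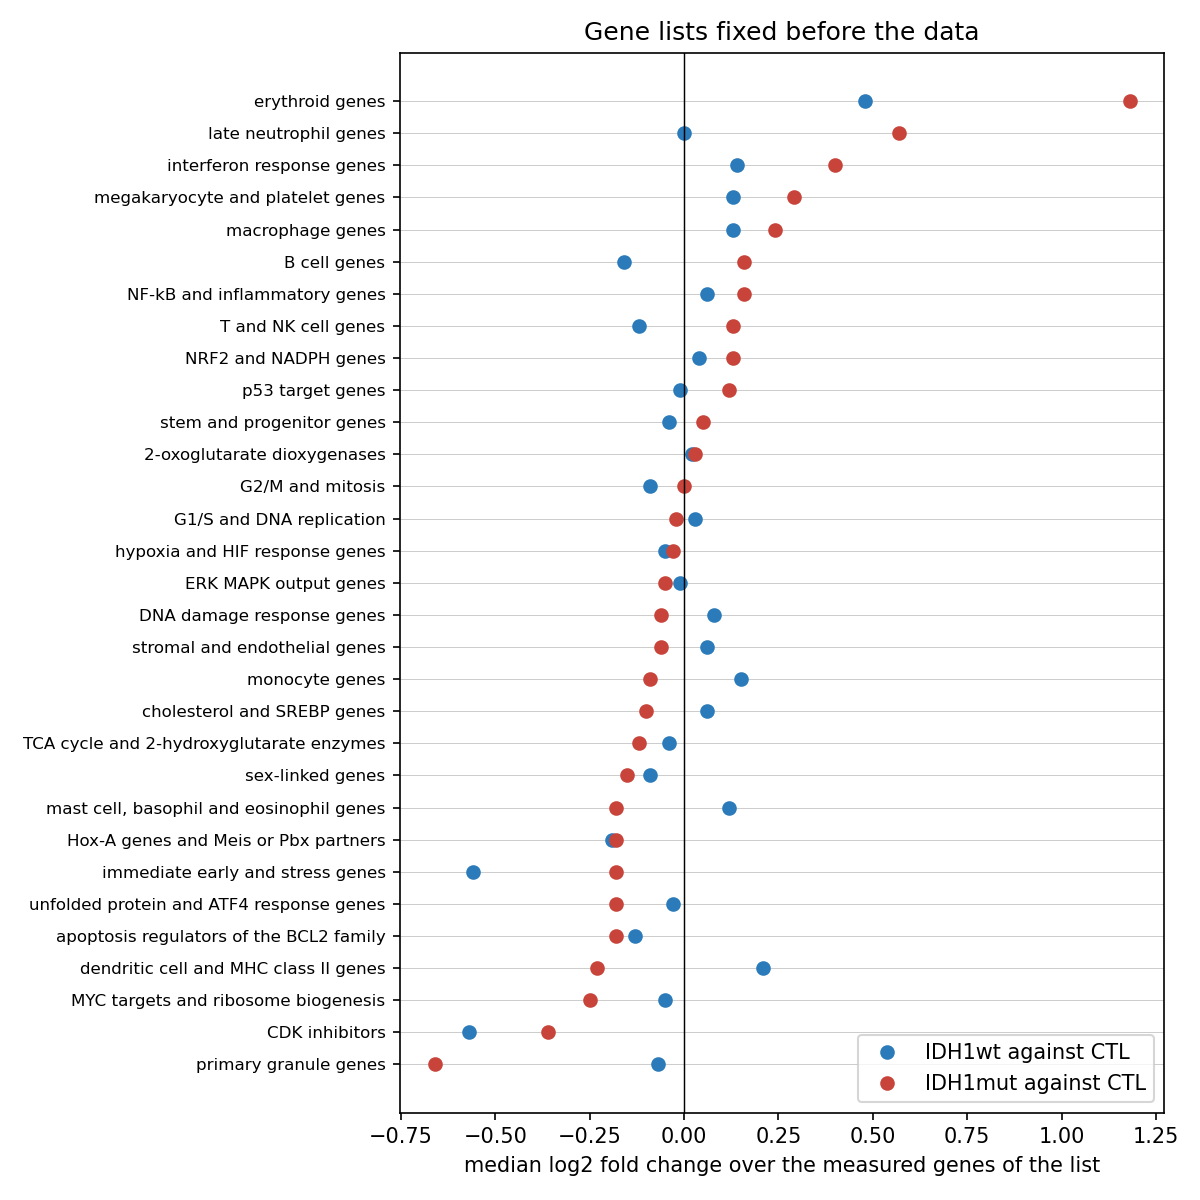
Median log2 fold change against CTL over the measured genes of each of 31 lists, with 1 point for IDH1mut and 1 for IDH1wt. Erythroid genes are highest in IDH1mut (1.18) and primary granule genes lowest (-0.66), while the IDH1wt medians of the late neutrophil and primary granule lists are 0.00 and -0.07.

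In IDH1wt against CTL, the heat shock genes Hspa1b (34.9-fold lower, -5.13 ± 0.28) and Hspa1a (30.8-fold lower, -4.94 ± 0.20) fell furthest, as near-identical copies with the uncertainty named above. Fosb (-2.38 ± 0.21) and Egr1 (-2.21 ± 0.21), both immediate early transcription factors, fell with them. The largest rise was that of Lrmda, 14.3-fold (3.84 ± 0.17), from 4.39 ± 0.20 to 8.24 ± 0.12. Late neutrophil genes rose in 1 of 21 members and primary granule genes fell in 0 of 14, with the same counts adjusted over the list alone. The member that rose was Mmp8, with a call lost without any 1 of 5 single arrays, at adjusted p up to 0.16 (without CTL replicate 1). Cdkn2a did not pass (-0.68 ± 0.21, adjusted p = 0.122).

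In this comparison 414 genes changed, 288 up and 126 down, and 83 of these changed at least 2-fold, 50 up and 33 down. The count was sensitive to single arrays, with 132 genes without CTL replicate 1, 145 without CTL replicate 3, 211 without IDH1wt replicate 2 and 145 without IDH1wt replicate 3. It was 17 in an unmoderated test per gene, 717 with an intensity trend and robust variances, and 1226 with array weights (714 up and 512 down).

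After Lrmda the largest rises were those of Bex1 (11.4-fold), Il17re (9.56-fold), Cela1 (8.98-fold), Stfa3 (7.95-fold), Erdr1 (5.34-fold), Pls3 (5.22-fold) and Ugt8a (4.94-fold). Slc15a2 (4.70-fold), Perp (4.55-fold), Klhl13 (4.41-fold) and Tceal8 (4.20-fold) followed, at adjusted p from 9.53e-07 to 0.0223. Lrmda, Bex1 and Slc15a2 were also among the 12 largest rises in IDH1mut. Beside Hspa1b, Hspa1a, Fosb and Egr1, the largest falls were those of Eya1 (5.54-fold), Crhbp (4.97-fold), H60c (4.74-fold), Pisd-ps3 (4.73-fold), Myl10 (4.64-fold), Clca1 (4.34-fold), Wdfy1 (4.04-fold) and Ptprg (3.97-fold). Klhl13 lost its call without CTL replicate 3 (adjusted p = 0.0521), Clca1 without any 1 of 4 single arrays (up to 0.0964, without CTL replicate 1) and Tceal8 without any 1 of 5 (up to 0.0799, without CTL replicate 3).

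Immediate early and stress genes fell in 8 of 16 members and rose in 0 (10 and 1 adjusted over the list alone), with a median of -0.56, and camera called the list (adjusted p = 8.51e-10; adjusted p = 0.544 with an estimated correlation). CDK inhibitors fell in 1 of 5 and rose in 0 (4 and 0 adjusted over the list alone), with a median of -0.57 (adjusted p = 0.0179; adjusted p = 0.544 with an estimated correlation). The member that fell was Cdkn1b (-0.57 ± 0.12), whose call was lost without any 1 of 5 single arrays, at adjusted p up to 0.149 (without CTL replicate 1). The call of the list was lost without CTL replicate 1 (adjusted p = 0.053) or IDH1wt replicate 1 (adjusted p = 0.0526) and among the brighter genes alone (adjusted p = 0.249).

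Interferon response genes rose in 3 of 30 and fell in 0 (8 and 0 adjusted over the list alone), with a median of 0.14 and a call at adjusted p = 0.000275 (adjusted p = 0.544 with an estimated correlation). The median was 0.24 without IDH1wt replicate 1 and 0.09 without IDH1wt replicate 2. Ifit3 rose by 0.74 ± 0.13 and Rsad2 by 0.57 ± 0.11; each lost its call without any 1 of 4 single arrays, at adjusted p up to 0.0738 and 0.0938, both without CTL replicate 3. Monocyte genes rose in 2 of 18 and fell in 0, the same adjusted over the list alone, with a median of 0.15 (adjusted p = 0.00522; adjusted p = 0.687 with an estimated correlation; adjusted p = 0.0519 among the brighter genes alone). Fcgr1 (0.74 ± 0.12), an immunoglobulin receptor, was 1 of them and lost its call without CTL replicate 1 (adjusted p = 0.0544).

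Erythroid genes had a median of 0.48 with 0 of 22 members risen or fallen, over all genes and over the list alone, and a call at adjusted p = 0.000141 (adjusted p = 0.687 with an estimated correlation). Without IDH1wt replicate 2 the median was 0.16 and the call was lost (adjusted p = 0.179), and without IDH1wt replicate 1 the median was 0.83. Dendritic cell and MHC class II genes had a median of 0.21 with 0 of 17 members changed (1 risen adjusted over the list alone) and a call at adjusted p = 0.0157 (adjusted p = 0.544 with an estimated correlation), lost without CTL replicate 1 (median 0.04, adjusted p = 0.0651) or IDH1wt replicate 2 (median 0.14, adjusted p = 0.0956) and among the brighter genes alone (adjusted p = 0.216). Mast cell, basophil and eosinophil genes rose in 1 of 19 and fell in 0 (4 and 0 adjusted over the list alone), at a median of 0.12 (adjusted p = 0.00522; adjusted p = 0.544 with an estimated correlation), and lost the call without IDH1wt replicate 2 (adjusted p = 0.104) and among the brighter genes alone (adjusted p = 0.249). Their median was 0.19 without CTL replicate 1 or CTL replicate 3 and 0.24 without IDH1wt replicate 1. On IDH1wt replicate 2 the median deviation was 0.53 for erythroid and 0.49 for mast cell, basophil and eosinophil genes, the highest of the IDH1wt arrays. With fry, the interferon (adjusted p = 0.199), monocyte (adjusted p = 0.373), erythroid (adjusted p = 0.502), dendritic cell (adjusted p = 0.262) and mast cell (adjusted p = 0.29) lists did not pass. The other 24 lists were not called by camera in this comparison, among them the cell cycle lists with 0 of 27 members changed in each. Fry also called Hox-A genes and partners as lower (adjusted p = 0.00012).

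The direct comparison of IDH1mut with IDH1wt asked which values differed between the groups with the mutant and the wild-type enzyme. Late neutrophil genes rose in 15 of 21 and fell in 0 (17 and 0 adjusted over the list alone), with Anxa1 at 1.57 ± 0.20, Mmp8 at 1.53 ± 0.14 and Fpr2 at 0.97 ± 0.11. Primary granule genes fell in 10 of 14 and rose in 1, the same adjusted over the list alone, with Cst7 at -1.46 ± 0.11 and Nkg7 at -1.05 ± 0.10; the member that rose was Fcnb (0.53). Sall2 (24.1-fold) and Mecom (8.47-fold) rose most, and Cdkn2a was 3.31-fold lower (-1.73 ± 0.21; adjusted p = 0.000506). Meis1 rose by 1.08 ± 0.16, Idh2 fell (-0.47 ± 0.10; adjusted p = 0.00814), and Cdkn1a (0.08 ± 0.11; adjusted p = 0.707) and Cdkn2b (-0.17 ± 0.11; adjusted p = 0.35) did not pass. Hoxa9 fell (-0.54 ± 0.14; adjusted p = 0.0311), a call lost without any 1 of 4 single arrays, at adjusted p up to 0.088 (without IDH1wt replicate 1).

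Between IDH1mut and IDH1wt 2363 genes changed, 1160 up and 1203 down, and 217 of them at least 2-fold. The count was 1475 without IDH1wt replicate 3, 1528 without IDH1mut replicate 2 and 276 in an unmoderated test per gene. Of the genes that rose in IDH1mut against CTL, 888 also rose against IDH1wt, and 859 of those that fell against CTL also fell against IDH1wt. Independent lists of these sizes would share 116.7 and 127.5, but both comparisons use the IDH1mut arrays, which adds to the overlap.

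Prrt4 (5.90-fold), Vpreb1 (5.76-fold), Dntt (5.50-fold), Chil1 (5.02-fold), Tmem178 (4.81-fold) and Igll1 (4.73-fold) rose next after Mecom. H60c (4.69-fold), Socs2 (4.54-fold), Fmnl2 (4.18-fold) and Dnah6 (4.09-fold) completed the 12, at adjusted p from 6.96e-07 to 0.00839. The largest falls were those of Stfa3 (-3.70 ± 0.19), Il17re (7.82-fold), Rhoj (6.92-fold), Mansc1 (4.56-fold), Ugt8a (4.26-fold) and Vmn2r26 (3.97-fold). As3mt (3.87-fold), Pls3 (3.71-fold), Prg2 (3.66-fold), Hnmt (3.65-fold), Perp (3.61-fold) and Ednrb (3.31-fold) followed, at adjusted p from 2.1e-06 to 0.00222.

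Both neutrophil lists were called, the late one at adjusted p = 5.46e-13 (adjusted p = 0.152 with an estimated correlation) and the primary granule one at adjusted p = 3.15e-07 (adjusted p = 0.152 with an estimated correlation). Monocyte genes fell in 9 of 18 and rose in 1 (11 and 1 adjusted over the list alone), with Cd14 at -0.91 ± 0.18 and Irf8, a factor of monocyte and dendritic cell development, at -0.87 ± 0.16 (list adjusted p = 0.000246; adjusted p = 0.469 with an estimated correlation). Itgam, which the late neutrophil list also holds, was the monocyte list member that rose (0.48). IDH1mut replicate 1 stood apart in this list, with a median deviation of 0.03 beside -0.40 and -0.23 on IDH1mut replicates 2 and 3, as it did for macrophage genes (0.33 beside 0.02 and -0.05). Dendritic cell and MHC class II genes fell in 8 of 17 and rose in 0, the same adjusted over the list alone, with Cd209a (-1.13 ± 0.12), Cd74 (-0.83 ± 0.16) and H2-DMa (-0.79 ± 0.11) down (adjusted p = 0.000345; adjusted p = 0.21 with an estimated correlation). Mast cell, basophil and eosinophil genes fell in 6 of 19 and rose in 0 (10 and 1 adjusted over the list alone), with Siglecf at -1.34 ± 0.14 (adjusted p = 0.000931; adjusted p = 0.358 with an estimated correlation).

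Interferon response genes rose in 12 of 30 and fell in 2 (16 and 5 adjusted over the list alone), with Ifit3 at 0.87 ± 0.13, Oasl2 at 0.85 ± 0.13 and Rsad2 at 0.81 ± 0.11, and the list was called at adjusted p = 0.000931 (adjusted p = 0.515 with an estimated correlation). MYC targets and ribosome biogenesis genes fell in 7 of 29 and rose in 0 (9 and 1 adjusted over the list alone), with Utp20 (-0.60 ± 0.13) and Cad (-0.55 ± 0.09) down (adjusted p = 0.000319; adjusted p = 0.268 with an estimated correlation). T and NK cell genes rose in 4 of 21 and fell in 1 (8 and 1 adjusted over the list alone; adjusted p = 0.000319; adjusted p = 0.152 with an estimated correlation; adjusted p = 0.0896 among the brighter genes alone). Cd247 (1.31 ± 0.18) and Cd3g (1.03 ± 0.20), parts of the T cell receptor complex, reached 4.77 and 5.97 in IDH1mut, and the costimulatory receptor Cd28 fell (-1.35 ± 0.15).

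Erythroid genes rose in 2 of 22 and fell in 0 over all genes (11 and 0 adjusted over the list alone), at a median of 0.67, with a call at adjusted p = 4.04e-06 (adjusted p = 0.563 with an estimated correlation; adjusted p = 0.122 with fry). The median was 0.32 without IDH1wt replicate 1. Of the pair, Nfe2 rose by 0.40 ± 0.09, and Trim10 (0.85 ± 0.25) lost its call without any 1 of 5 single arrays, at adjusted p up to 0.16. Immediate early and stress genes rose in 4 of 16 and fell in 1 (7 and 1 adjusted over the list alone), among them Hspa1b (1.52 ± 0.28), Btg2 (0.77 ± 0.12) and Klf6 (0.77 ± 0.11), while Jun fell (-0.78 ± 0.16). That call (adjusted p = 0.0107; adjusted p = 0.706 with an estimated correlation; adjusted p = 0.122 with fry) was lost without IDH1wt replicate 1 (adjusted p = 0.156) or IDH1mut replicate 1 (adjusted p = 0.119). The other 21 lists were not called by camera, and for CDK inhibitors 1 of 5 rose and 1 fell, the same adjusted over the list alone. Fry also called p53 targets and NRF2 genes (each adjusted p = 0.0177) and Hox-A genes and partners (0.0471) as higher. It called sex-linked genes as lower (adjusted p = 0.0365).

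Many of the genes that changed in IDH1wt changed the same way in IDH1mut: 202 rose and 82 fell in both, which was 68.6% of the IDH1wt calls. Independent lists would share 29 and 13.4, an expectation that leaves out the CTL arrays common to both. Lrmda, Bex1, Slc15a2, Hspa1a, Hspa1b, Egr1 and Eya1 were among the largest changes of both. Across genes, which are not independent replicates, the log2 fold changes of the 2 comparisons correlated at r = 0.558 (rho = 0.492), beside 0.499 for simulated unchanged groups. That gap lay within the spread, with a jackknife SE of 0.084 and r = 0.485 without IDH1wt replicate 2. The simulated r follows from the shared controls alone. It is no reference for groups with changed genes, so the gap does not measure how far the 2 sets of changes agree. The covariance of the 2 sets of fold changes was 0.053, beside 0.0088 in the simulation, a difference of 0.0443. The 3 CTL arrays were not split, since 1 part would have kept a single array, and part of the overlap may come from the shared controls.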

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

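All alternatives were chosen before the data were examined. The counts of changed genes stayed within 1.5 times the reported ones under the mean of probe sets, all probe sets, the brighter genes, a repeated quantile normalisation, centring and the fit on 6 arrays. For the brighter genes these counts were 3991, 580 and 2827 of only 8865 genes tested, so a larger share was called than over all 17731 genes. With the replicate number as a block they were 3383 (IDH1mut against CTL), 314 (IDH1wt against CTL) and 2035 (IDH1mut against IDH1wt) genes and 6, 7 and 11 lists, and the immediate early list of IDH1mut against CTL lost its call (adjusted p = 0.0632). Deviations from the group means correlated between -0.086 and 0.026 for same-numbered arrays of different groups, and between -0.075 and 0.084 for the other pairs. These values show no pairing by number across genes at large, and a pairing that touches few genes is not excluded. An added 2-fold threshold, stricter by construction, left 413, 83 and 217 genes. An unmoderated test per gene called 2074, 17 and 276, of which the moderated fit also called 1829, 13 and 256. For IDH1wt against CTL an intensity trend with robust variances gave 717 and array weights 1226; the cause was not tested.

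An estimated correlation called 0 of 31 lists in each comparison, where camera with the preset value called 6, 7 and 10 and fry called 14, 3 and 12. Among the brighter genes IDH1wt against CTL called 3 lists, with fewer genes tested. Leaving out 1 array in turn gave 2370 (without CTL replicate 1) to 3390 genes, 132 (without CTL replicate 1) to 570 genes and 1475 (without IDH1wt replicate 3) to 2050 genes, with fewer samples. The lists called ranged from 5 to 10 and from 5 to 12, both highest without CTL replicate 2, and from 10 to 14. The correlation of the fold changes against CTL ranged from 0.485 to 0.599. Over 5797 values of named genes under alternatives, 5313 kept their side of the threshold, 368 lost a call, 116 gained one and 0 of the called ones changed sign; signs of uncalled values were not scored. Of 299 values of called lists, 250 kept the call, 49 lost it and 0 turned. RMA values carry no background level per probe set, so a gene near the low end, such as Hoxa9, has no tested presence.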

Other observations

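Some single genes that changed in IDH1wt against CTL also differed between the 2 IDH1 groups. Against CTL, Stfa3 was 7.95-fold higher in IDH1wt, and it was lower in IDH1mut than in IDH1wt by 3.70 ± 0.19 on the log2 scale; Il17re, Pls3, Ugt8a and Perp also rose in IDH1wt and lay lower in IDH1mut than in IDH1wt. H60c fell in IDH1wt (-2.25 ± 0.22) and was 4.69-fold higher in IDH1mut than in IDH1wt. Among genes of the marrow niche, Acta2 (1.44 ± 0.16) and Cxcl12 (1.05 ± 0.14) rose in IDH1mut against CTL while Vcam1 fell (-0.99 ± 0.12), in cells sorted for the vector's fluorescence. Of 17 further heat shock genes, 6 fell and 3 rose in IDH1mut against CTL, with Dnajb4 (0.81) the largest move, and 1, Hspa8 (-1.25), fell in IDH1wt against CTL.

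Tests chosen only after the result was seen were those on immediate early genes, erythroid genes and B-lineage genes. The rules of the heat shock, chromosome and sample split tests were set before their own outcomes. The heat shock and chromosome tests still address gene changes that had been seen in these data. With 3 arrays against 3 there are 10 splits, too few for a share under 0.05. In IDH1mut against CTL 1 of the 10 splits, the real one, gave 3663 genes and the highest other gave 0. The same held for IDH1wt against CTL (1 split, 414 genes, highest other 0) and for IDH1mut against IDH1wt (1 split, 2363 genes, highest other 0).

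Hspa1a, Hspa1b, Jun, Egr1 and Fosb were lower in both IDH1 groups than in CTL. For a general heat shock response in the CTL cells, a shift of -0.5 or lower had been required of 17 other heat shock genes. Their median log2 fold change was -0.08 in IDH1wt (95% bootstrap interval -0.13 to 0.04) and 0.03 in IDH1mut (-0.38 to 0.15). These values argue against a shift shared by most of the 17. The intervals run over genes and leave out the spread between arrays. Hspa1a and Hspa1b were not among the 17, so a response limited to few heat shock genes is not excluded. An immediate early response to handling of the CTL cells stays open: the other 11 members of that list had a median of -0.38 in IDH1wt (-0.57 to 0.24) and 0.06 in IDH1mut (-0.29 to 0.33), and members went both ways. A response to handling and an effect of the IDH1 vectors cannot be told apart for these 5 genes, because the labels give no handling time and each group may have been sorted together. An effect of either IDH1 protein was not tested separately.

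Erythroid genes were higher in IDH1mut than in CTL, and a different share of erythroid cells in each array is a candidate explanation. The 22 members deviated together from their group means, with a median pairwise correlation of 0.77 where 1000 random lists matched on mean reached at most 0.29. The IDH1wt arrays held 86.3% of the members' squared deviations, and without them the correlation was 0.25, within the range of the random lists (up to 0.40), so the members moved together in the IDH1wt arrays and this does not settle the difference between IDH1mut and CTL. Whether IDH1mut and CTL differed in erythroid share or in expression per cell stays open, since the sort kept vector-carrying cells and erythroid progeny of those cells may have passed it.

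Vpreb1, Igll1 and Dntt were higher in IDH1mut than in both other groups. The other 19 members of the B cell list had a median of 0.10 against CTL (95% bootstrap interval -0.20 to 0.34) and 0.35 against IDH1wt (-0.03 to 0.50). These 19 were what remained after the genes that rose most were taken out, so their values exclude nothing. The whole list had an estimated inter-gene correlation of 0.55, and its median deviation was highest on IDH1mut replicate 3 (0.72). A larger share of B-lineage cells, a share of early B precursors alone, and expression of these genes in other cells all stay open.

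Xist fell in IDH1mut, and the hypothesis that X-linked genes were less silenced was tested on genes brighter than the median. The median log2 fold change against CTL of 240 X-linked genes minus that of 8610 autosomal genes was 0.02 (95% bootstrap interval -0.05 to 0.07), below the 0.1 set beforehand. On these arrays the values speak against a general rise of X-linked genes. The interval runs over genes and leaves out the spread between arrays.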
